A study of Mus musculus with 6 samples.

How the data were processed

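Total RNA of mouse spleen had been extracted with an organic reagent, cleaned on columns and labelled with biotin, per the labels' protocols, and each sample was measured on 1 Illumina whole-genome bead array. The 6 arrays formed 3 groups of 2, taken from the sample titles: saline, cadmium chloride at 5 µmol/kg and cadmium chloride at 10 µmol/kg. The intensity of each probe was the authors' deposited mean bead signal on a linear scale. These intensities were deposited in a table described as not normalized. Their lowest value was −20.15, and the sorted values of the 6 arrays differed by at most 0.243 units, so background subtraction and quantile normalization had taken place before deposit. The software behind them is not given in the sources used here. The authors also deposited a detection p-value for each probe and array, which compares its signal with negative-control probes. The deposited series matrix held intensities identical to those in the first table for 45279 of the 45281 probes.

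Background correction and normalization used the neqc function of limma 3.58.1 in R 4.3.3, which fits a normal and exponential model with the negative-control level inferred from the detection p-values, adds an offset of 16, normalizes by quantiles and takes log2. This method was chosen for raw signals and was kept for signals that were already normalized. A fold change on this scale understates the change of dim genes because of the offset. Probes with a detection p-value under 0.05 on at least 2 arrays were kept, which left 18960 probes. Gene symbols came from the platform annotation, which gave 1 symbol for 34885 probes, several for 18 and none for 10378. Symbols were looked up through gene identifiers in a mouse RefSeq table of the assembly GRCm38.p6. There 34807 were found, none of them renamed, and 96 were not found. A probe without a symbol was tested under its own name, and a probe with several symbols was named after none. The probe with the highest mean stood for each gene, which gave 10823 named genes and 2736 unnamed probes, 13559 in all. Genome positions were not used here.

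One linear model with a mean for each group was fitted to all 6 arrays with limma, so that the 3 comparisons shared 1 estimate of the spread, with 3 residual degrees of freedom and 3.639 prior degrees of freedom. Moderated tests compared each dose with saline, the doses with each other, and all 3 groups at once with an F test. The p-values were adjusted by the Benjamini-Hochberg method over the 13559 genes and probes, with a threshold of 0.05. A group in which no array detected a gene has only a bound, and its fold change is then given as at least a value, with the detection limit of each array in place of a lower signal.

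The 32 gene lists covered responses to metal, oxidation and other stress, metabolic and cell cycle genes, and markers of the cell types that spleen tissue and its surroundings hold. A list of sex-linked genes served as a check only, and the other 31 lists, each with at least 5 measured members, were tested with camera at a preset correlation of 0.01 between genes. Camera with a correlation estimated from the residuals, and fry, which asks whether the genes of a list move on balance in 1 direction, were alternatives. The groups, tests, gene lists, named-gene rule and a set of other settings were fixed before the data were examined. Because no gene passed the threshold, the rule named the 5 genes with the smallest unadjusted p in each direction of each comparison, passing over predicted genes, the 2 members of each list with the highest mean signal, and Mt1, Mt2 and Hmox1 in every case. Other list members named in the text were chosen after their values were seen, mostly among members with an unadjusted p under 0.05. Ifit3, Ins2 and Cela2a were chosen after their values were seen without that condition.

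The other settings changed the background correction, the normalization, the offset, the filter, the choice of probe, the arrays fitted, the variance model and the threshold, added the replicate number as a block, and left out each array in turn. After the data were seen, fits were added with the mean log2 level of 24 pancreatic acinar genes as a covariate, with only the 4 arrays on which these genes were bright, with only the other 2 arrays, and with the replicate numbers of 1 group exchanged. Responses to the doses share the saline arrays, so all 6 arrays were simulated 100 times with no change, from the residual standard deviation of each gene, and both simulated doses were compared with the same simulated saline arrays.

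The tests were tried on simulated arrays built from the measured gene means and moderated standard deviations, with 200 of the 13559 genes changed. Of the changes of 2-fold, 6.27% were recovered for 5 µmol/kg against saline, 6.64% for 10 µmol/kg against saline and 6.08% for 10 against 5 µmol/kg. Of the changes of 4-fold, 83.5%, 85.4% and 85.0% were recovered in that order, and of the changes of 8-fold, 97.3%, 98.0% and 97.7%. False calls made up 6.71%, 7.50% and 7.48% of all calls. A list of cell cycle genes shifted by 0.5 on the log2 scale was called in 20 of 20 simulations of 10 µmol/kg against saline by camera with the preset correlation, in 0 of 20 with an estimated correlation and in 3 of 20 by fry. With no list shifted, camera with the preset correlation made 1 call in 620 tests of lists. Simulated genes varied independently, which genes of 1 list need not do. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.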

Results

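Gene expression was measured in the spleen of ICR mice, an outbred stock, 24 h after 1 subcutaneous injection of cadmium chloride. The animals were 28 days old and received 5 or 10 µmol of the salt per kg body weight in 200 µL of saline, or saline alone. Each of the 3 groups was represented by 2 bead arrays. The labels gave 7 to 8 animals per group and did not say whether an array held the RNA of 1 animal or of several, so the p-values measure only the spread between these arrays, which may be technical. Of the 45281 probes, 18561 were detected on saline array 1 and between 16265 and 16901 on each other array. The lowest detected signal was 7.56 on saline array 1 and between 9.61 and 10.63 on the others. The number of arrays limits the precision of every comparison.

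The arrays differed first in genes of the exocrine pancreas, an organ that adjoins the spleen. All 24 measured acinar genes, among them the amylase Amy2a5 and the elastase Cela1, were detected on saline array 2, on both arrays at 5 µmol/kg and on array 2 at 10 µmol/kg, where their mean log2 signals were 12.80, 12.43, 11.45 and 12.20. On saline array 1 and on array 1 at 10 µmol/kg the means were 4.80 and 5.00, with 7 and 11 of the 24 genes detected. The median gene was at least 320-fold brighter on saline array 2 than on saline array 1, and at least 196-fold brighter on array 2 than on array 1 at 10 µmol/kg. These genes gave 3.63% of the total signal on saline array 2 and 0.00655% on saline array 1. The same arrays stood apart over all genes. Across genes, which are not independent replicates, saline array 1 correlated more closely with array 1 at 10 µmol/kg (Pearson's r = 0.980) than with saline array 2 (r = 0.926), and the 2 arrays at 10 µmol/kg had r = 0.929. The median difference between the 2 arrays of a group was 0.36 on the log2 scale for saline, 0.23 for 5 µmol/kg and 0.35 for 10 µmol/kg.

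**Figure D1:**
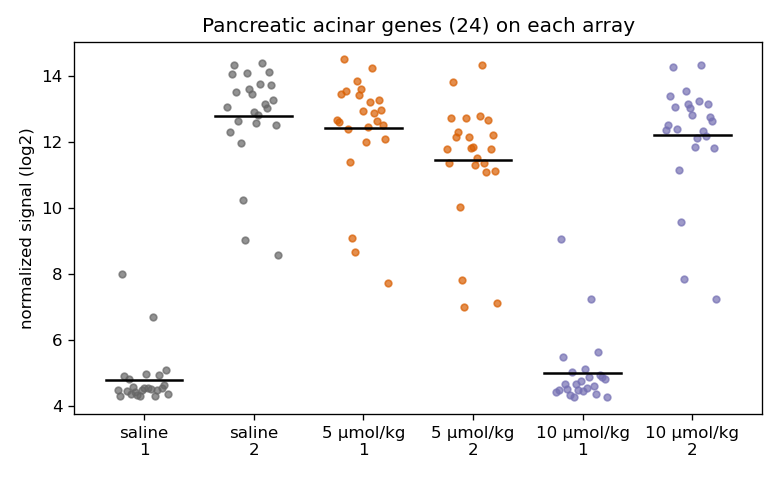
Normalized log2 signal (vertical axis) of 24 pancreatic acinar genes on each of the 6 arrays (horizontal axis), with 1 point per gene and a line at the mean. The means lie at 4.80 and 5.00 on array 1 of the saline group and array 1 of the 10 µmol/kg group, and between 11.45 and 12.80 on the other 4 arrays.

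Cadmium at 5 µmol/kg was compared with saline to see which spleen genes responded to the lower dose. No single gene passed. As groups, genes of cell division, red cell formation and mitochondrial respiration were called higher and B cell and plasma cell genes lower by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.757 for each). Each of these 5 calls was lost without saline array 1. The genes with the smallest p on the higher side were Oosp2, an oocyte-secreted protein (log2 difference 1.47 ± 0.25 SE), the pseudogene Cyp4b1-ps2 (1.95 ± 0.36), the ribosomal protein Rpl7a (1.75 ± 0.35), the interferon-induced modifier Isg15 (1.59 ± 0.32) and Lefty1, of the TGF-beta family (2.30 ± 0.49). On the lower side they were Pced1a (−1.29 ± 0.25), the oxysterol-binding protein Osbp (−1.49 ± 0.30), Siglech, a surface lectin of plasmacytoid dendritic cells (−1.33 ± 0.27), the transcription factor Arid3a (−1.17 ± 0.25) and the kinase Map3k12 (−1.10 ± 0.24). Another probe of Siglech, of Map3k12 and of Pced1a differed in the opposite direction. Oosp2 and Lefty1 were detected on only 1 of the 2 saline arrays, and Map3k12 on only 1 of the 2 arrays at 5 µmol/kg. The differences of these genes thus rest partly on signals below the detection limit. None of the 10 passed, and 0 of 13559 genes and probes did in limma's moderated test (smallest adjusted p = 0.525). At an unadjusted p under 0.05 there were 1257 genes, 621 higher and 636 lower, or 9.27% of those tested. The groups did not overlap for 47.0% of genes, where chance gives 33.3%.

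Of the 31 gene lists, 10 were called higher and 3 lower at 5 µmol/kg by camera with the preset correlation, and none with an estimated correlation (smallest adjusted p = 0.757) or by fry (smallest adjusted p = 0.364). Cell cycle and DNA replication genes had a median log2 difference of 0.48, with 36 of 38 members above saline (camera adjusted p = 1.81e-05, and 0.757 with an estimated correlation). The kinetochore histone Cenpa (0.50 ± 0.24) and Birc5 (0.57 ± 0.34) were its brightest members, and Ccne2 (1.54 ± 0.39) and Aurkb (1.22 ± 0.34), a cyclin and a mitotic kinase, were among 5 members with an unadjusted p under 0.05. Erythroid genes had a median of 0.35 over 30 members (adjusted p = 0.000278, and 0.757 with an estimated correlation). Their brightest members, Slc4a1 (−0.07 ± 0.23) and Hba-a1 (−0.12 ± 0.23), were not higher. They read between 14.09 and 14.51 on all 6 arrays, near the top of the scale. Their deposited signals reached 23266 and 21394, below the highest on the arrays, 26609, so only a large increase would have been out of range. Fech, the last enzyme of haem synthesis (1.60 ± 0.39), and the Rh glycoprotein Rhag (1.60 ± 0.35) were among 8 erythroid members with an unadjusted p under 0.05. Genes of oxidative phosphorylation had a median of 0.33, with 56 of 66 above saline (adjusted p = 1.64e-05, and 0.757 with an estimated correlation). Without saline array 1, the medians of the cell cycle, erythroid and oxidative phosphorylation genes were −0.12, −0.048 and 0.09, and none was called. Without saline array 2 the medians were 0.97, 0.79 and 0.53, and without array 1 at 5 µmol/kg they were 0.16, 0.18 and 0.25. With the acinar level as a covariate, a fit chosen after the data were seen, they were 0.26, 0.22 and 0.17, and the 3 lists were called (adjusted p = 0.923, 0.902 and 0.902 with an estimated correlation).

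Interferon-response genes had a median of 0.20 at 5 µmol/kg, with 18 of 27 above saline (camera adjusted p = 0.0143, and 0.757 with an estimated correlation). Without array 2 at 5 µmol/kg the median was 0.05 and the call was lost, as it was without saline array 2. Isg15 was among 5 members with an unadjusted p under 0.05, and the brightest were Rsad2 (−0.19 ± 0.39) and Irgm1 (−0.09 ± 0.25), of which another Irgm1 probe differed in the opposite direction. Neutrophil and granulocyte precursor genes had a median of 0.18 over 29 members (adjusted p = 0.0121, and 0.757 with an estimated correlation). Ms4a3 (1.74 ± 0.40) and the granule protease Elane (1.36 ± 0.38) were among the 5 members with an unadjusted p under 0.05, and the brightest, S100a8 and Ltf, differed by 0.27 ± 0.24 and −0.38 ± 0.32. The list median was 0.0077 without array 2 at 5 µmol/kg, and the call was also lost without saline array 2. The other lists called higher were pancreatic acinar cells (median 3.43), cholesterol synthesis and uptake (0.36), proteasome subunits (0.23), NRF2 antioxidant and glutathione (0.15) and ribosomal proteins (0.08). Those called lower were plasma cells (−0.38), circadian clock (−0.36) and B cells (−0.21). For each of these 8 lists the adjusted p was 0.757 with an estimated correlation, and leaving out at least 1 array ended the call. In those fits medians ran from −0.56 to −0.071 for B cells and −0.63 to −0.26 for plasma cells. They ran from −0.52 to −0.25 for the circadian clock and 0.095 to 0.33 for proteasome subunits. The acinar covariate ended the calls of the proteasome (median 0.12), NRF2 (0.060), ribosomal (0.065) and B cell (−0.18) lists. It also ended that of the acinar list (median 0.044), which was fixed in advance because the covariate is the mean of those genes. The same fit called megakaryocyte and platelet genes higher (median 0.28, camera adjusted p = 0.00269, and 0.902 with an estimated correlation). Without the covariate that list had a median of 0.18 and was not called (camera adjusted p = 0.0844). Adjusted over the list alone, 2 genes passed, Nsdhl of cholesterol synthesis (1.13 ± 0.26, adjusted p = 0.0462) and Siglech of the dendritic cell list, and 0 passed over all genes. This adjustment, here and below, does not correct for the number of lists, so some passes can come by chance. Nsdhl read 4.52 and 4.76 on the saline arrays, near their detection limits of 4.64 and 4.75.

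**Figure D2:**
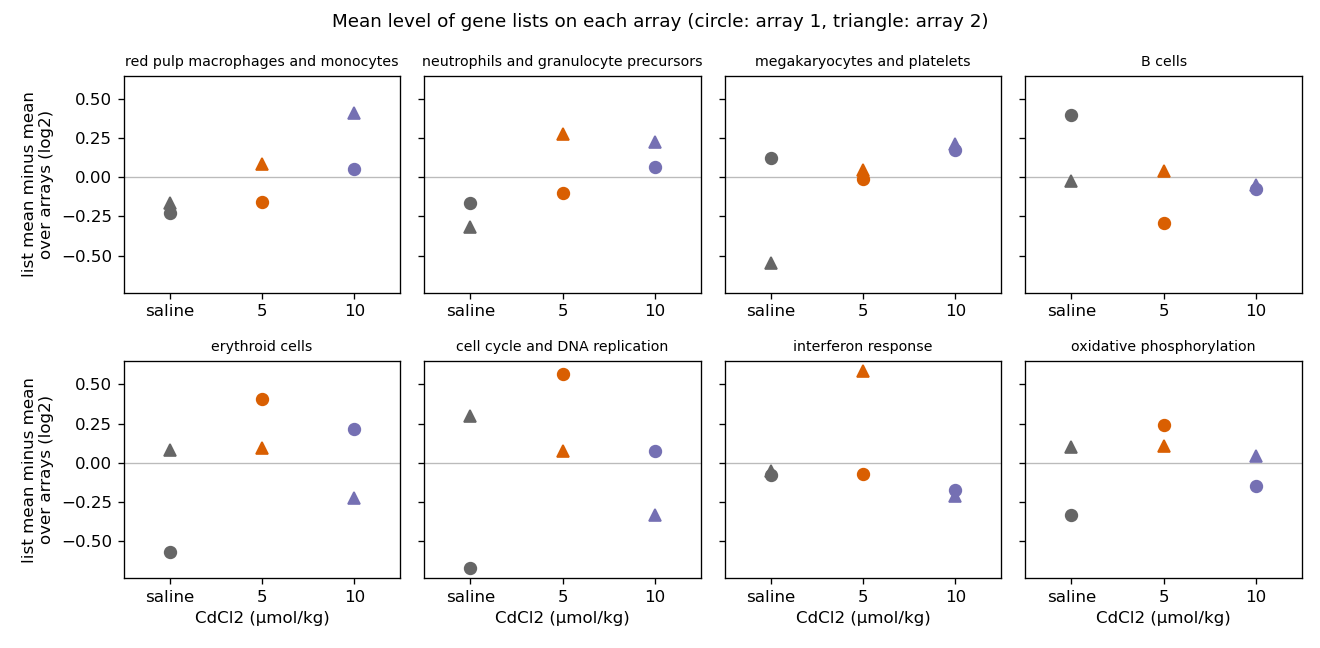
Mean log2 level of 8 gene lists on each array, relative to the mean over the 6 arrays (vertical axis), by dose of cadmium chloride in µmol/kg (horizontal axis), with circles for array 1 and triangles for array 2 of each group. Both arrays at 10 µmol/kg lie above both saline arrays for the red pulp macrophage and the neutrophil lists, whereas saline arrays 1 and 2 lie apart for the erythroid and cell cycle lists.

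Cadmium at 10 µmol/kg was compared with saline in the same way for the higher dose. No single gene passed here either. Gene lists of red pulp macrophages and monocytes, of neutrophils and granulocyte precursors, and of megakaryocytes and platelets were called higher, and the B cell list lower, by camera with the preset correlation. None of these 4 lists was called with an estimated correlation (adjusted p = 0.82 for each), and the platelet and B cell calls were lost in some fits that left out 1 array. The genes with the smallest p on the higher side were the complement component C1qb (log2 difference 1.16 ± 0.23 SE), transferrin, Trf (1.45 ± 0.30), the neutrophil granule protease Prtn3 (1.28 ± 0.29), the membrane protein Ms4a6d (1.84 ± 0.41) and Tspyl1 (1.09 ± 0.25). On the lower side they were Osbp (−1.28 ± 0.30), Pnkd (−0.88 ± 0.22), the interferon-inducible Ifi213 (−1.13 ± 0.30), the germinal centre repressor Bcl6 (−0.89 ± 0.25) and Micall1 (−0.74 ± 0.23). None passed, nor did any of the 13559 genes and probes in limma's moderated test (smallest adjusted p = 1). At an unadjusted p under 0.05 there were 221 genes, 135 higher and 86 lower, or 1.63% of those tested. The groups did not overlap for 22.5% of genes, against 33.3% by chance.

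Camera with the preset correlation called 6 lists higher and 1 lower at 10 µmol/kg, and with an estimated correlation none (smallest adjusted p = 0.82). Red pulp macrophage and monocyte genes had a median log2 difference of 0.40, with 22 of 25 members above saline (camera adjusted p = 1.45e-09, and 0.82 with an estimated correlation). The 3 chains of complement C1q, C1qa (1.01 ± 0.28), C1qb and C1qc (0.92 ± 0.26), the mannose receptor Mrc1 (0.91 ± 0.26) and Spic, the transcription factor of red pulp macrophages (0.72 ± 0.23), were among 8 members with an unadjusted p under 0.05, of which the scavenger receptor Marco was lower (−0.84 ± 0.35). The brightest members, Lyz1 and Vcam1, differed by −0.06 ± 0.25 and 0.34 ± 0.28, with another Lyz1 probe opposite in sign. C1qb passed when adjusted over the list alone (adjusted p = 0.042), and 0 genes passed over all genes. Neutrophil and granulocyte precursor genes had a median of 0.23, with 23 of 29 above saline (camera adjusted p = 1.5e-06, and 0.82 with an estimated correlation). Ms4a3 (1.55 ± 0.40), Elane (1.54 ± 0.38), Ctsg (1.30 ± 0.39) and Prtn3, all made in granulocyte precursors, were among the 7 members with an unadjusted p under 0.05, while S100a8 and Ltf, the brightest, differed by 0.16 ± 0.24 and −0.49 ± 0.32. Both lists were called higher in each fit that left out 1 array, although the macrophage median was 0.17 without array 2 and 0.71 without array 1 at 10 µmol/kg. The macrophage median was 0.33 between the arrays with little acinar signal and 0.56 between the arrays numbered 2, and the neutrophil median was 0.27 and 0.31, values of 1 array against 1 array that were not tested.

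Megakaryocyte and platelet genes had a median of 0.40 at 10 µmol/kg, with 18 of 19 above saline (camera adjusted p = 1.5e-06, and 0.82 with an estimated correlation), and the call was lost without saline array 2, where the median was 0.14, against 0.71 without saline array 1. It was 0.068 between the arrays with little acinar signal and 0.71 between the arrays numbered 2. The platelet chemokine Ppbp differed by 0.94 ± 0.48 and the tubulin Tubb1 by 0.24 ± 0.29. B cell genes had a median of −0.29, with 15 of 17 below saline (adjusted p = 0.00552, and 0.82 with an estimated correlation). Their brightest members were Cd79b (−0.14 ± 0.33, with another probe opposite in sign) and Fcmr (−0.38 ± 0.30). The B cell call was lost without saline array 1 (median −0.11) and without array 1 at 10 µmol/kg (−0.25), and the median was −0.52 without saline array 2. It was −0.61 between the arrays with little acinar signal and −0.060 between the arrays numbered 2. Erythroid genes had a median of 0.16 (adjusted p = 0.00512, and 0.843 with an estimated correlation), but the difference was 0.90 between the arrays with little acinar signal and −0.50 between the arrays numbered 2, and the call was lost without array 1 of either group. Cholesterol genes (median 0.23) and glucocorticoid-responsive genes (0.19) were also called higher, each with an adjusted p of 0.82 with an estimated correlation, and each call was lost without either saline array. Leaving out 1 array, the glucocorticoid median ran from 0.027 to 0.43. Fdps of cholesterol synthesis differed by 0.56 ± 0.24, with another probe of it opposite in sign.

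Genes that respond to cadmium in many tissues were examined in every comparison. The metallothionein Mt1, which binds the metal, had mean log2 signals of 12.32 ± 1.20 (SD, n = 2) in saline, 12.30 ± 0.09 (SD, n = 2) at 5 µmol/kg and 12.17 ± 0.15 (SD, n = 2) at 10 µmol/kg. Its difference from saline was −0.03 ± 0.52 SE at 5 µmol/kg (95% interval −1.26 to 1.21) and −0.15 ± 0.52 at 10 µmol/kg (−1.39 to 1.08). These intervals do not exclude increases of up to 2.31-fold and 2.11-fold. The saline arrays themselves read 11.48 and 13.17, and without saline array 2 the differences were 0.82 and 0.69. Mt2, measured by a dim probe, differed by −0.03 ± 0.40 and −0.27 ± 0.40. Haem oxygenase, Hmox1, differed by 0.26 ± 0.30 and 0.45 ± 0.30. The metal-response list of 7 genes, with the transcription factor Mtf1 at 0.60 ± 0.28 and at 0.25 ± 0.28 (opposite in sign by another probe at 10 µmol/kg), was not called at either dose against saline (camera adjusted p = 0.125 and 0.987). In the NRF2 list the brightest member, Gpx1, had the highest signal of the scale, 26609, on 5 of the 6 arrays, so its response could not be measured, and Fth1, also near the top, differed by 0.09 ± 0.25 at 5 µmol/kg. None of these genes passed in any comparison.

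**Figure D3:**
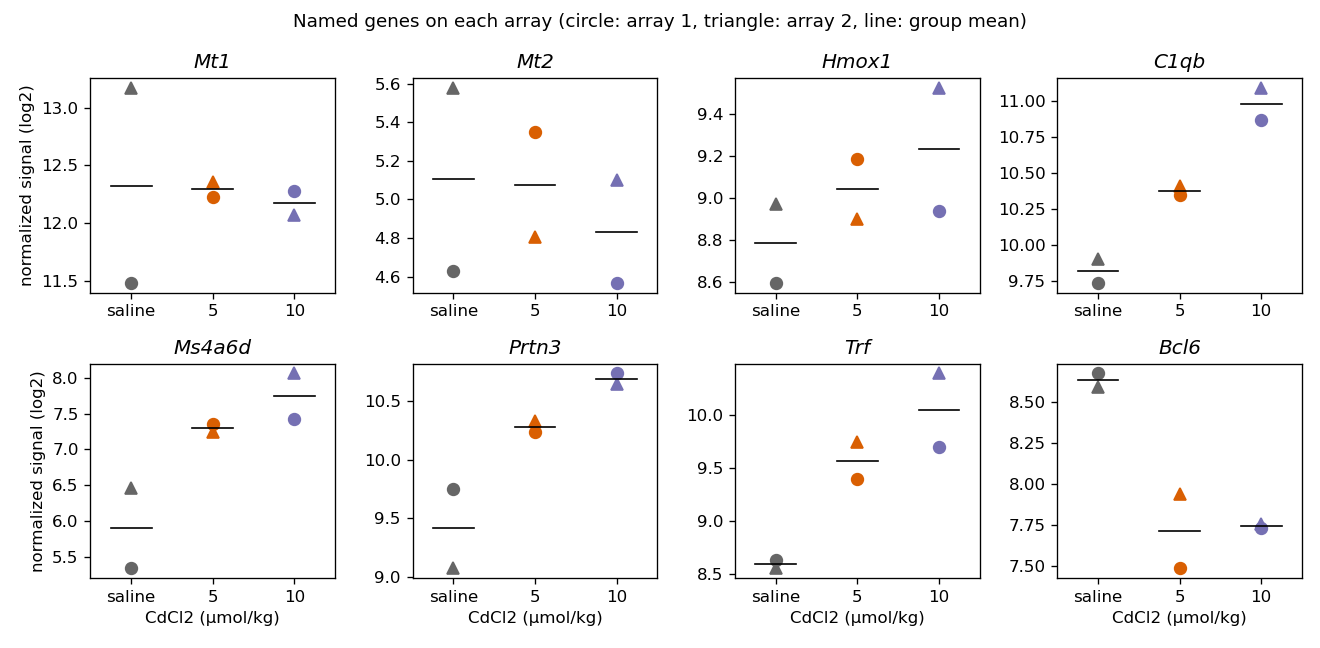
Normalized log2 signal (vertical axis) of Mt1, Mt2, Hmox1 and 5 genes named for small p in the comparison of 10 µmol/kg with saline, by dose of cadmium chloride in µmol/kg (horizontal axis), with circles for array 1, triangles for array 2 and a line at each group mean. Mt1 lies at 11.48 and 13.17 on the saline arrays, and C1qb lies higher on both arrays at 10 µmol/kg than on both saline arrays.

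The doses were compared with each other to see whether the response differed between them. Interferon, cell division and respiration genes were called lower as groups at 10 than at 5 µmol/kg, and macrophage genes higher, by camera with the preset correlation. None of the 4 was called with an estimated correlation (adjusted p = 0.689 for each), and only the respiration call was kept in each fit that left out 1 array. The genes with the smallest p that were higher at 10 µmol/kg were Zfp871 (at least 2.57-fold, not detected at 5 µmol/kg), the microtubule protein Mapt (log2 difference 1.14 ± 0.29 SE), Pced1a (0.89 ± 0.25), Tbc1d22b (at least 1.43-fold) and Prpsap2 (at least 1.51-fold). Those lower were the erythroid membrane protein Tspo2 (−1.56 ± 0.31), Oosp2 (−1.18 ± 0.25), Isg15 (−1.40 ± 0.32), the sterol enzyme Nsdhl (−1.01 ± 0.26) and Usp18, a protease that removes Isg15 (−1.60 ± 0.45). Another probe of Nsdhl and of Pced1a differed in the opposite direction. Nsdhl was detected on only 1 of the 2 arrays at 10 µmol/kg. In limma's moderated test 0 genes passed (smallest adjusted p = 0.981), and 130 had an unadjusted p under 0.05, 66 higher and 64 lower. Camera with the preset correlation called 5 lists higher and 8 lower, none of them with an estimated correlation (adjusted p = 0.689 for each). Interferon-response genes had a median of −0.42, with 23 of 27 below 5 µmol/kg (camera adjusted p = 5.2e-07), and the call was lost without array 2 at 5 µmol/kg, where the median was −0.11. Cell cycle genes had a median of −0.39, with 36 of 38 lower (adjusted p = 1.7e-07), and the call was lost without array 2 at 10 µmol/kg (median −0.13). Red pulp macrophage genes had a median of 0.31, with 20 of 25 higher (adjusted p = 0.000149), and this call too was lost without array 2 at 10 µmol/kg (median 0.21). Proteasome subunits (−0.22, with Psmb4 at −0.25 ± 0.24 and Psmd4 at 0.21 ± 0.29) and oxidative phosphorylation genes (−0.23, with Atp5b at 0.16 ± 0.41 and Atp5g3 at −0.26 ± 0.23) were called lower in each fit that left out 1 array. The oxidative phosphorylation median was −0.12 without array 1 and −0.38 without array 2 at 10 µmol/kg, and −0.090 with the acinar level as a covariate, a fit chosen after the data were seen. Glucocorticoid-responsive genes (0.29), plasma cells (0.25), endothelial cells (0.17) and the circadian clock (0.16) were also called higher, and acinar cells (−3.60), metal response (−0.29), erythroid cells (−0.18) and NRF2 (−0.11) lower. Each of these 8 calls was lost or turned in at least 1 fit that left out 1 array. In those fits medians ran from 0.081 to 0.40 for plasma cells, 0.043 to 0.33 for endothelial cells and 0.082 to 0.34 for the circadian clock. The acinar covariate ended the calls of the metal response (median −0.16), NRF2 (0.029) and endothelial (0.15) lists. It also ended that of the acinar list (median −0.018), as it had to, being the mean of those genes. Adjusted over the list alone, Tspo2 of the erythroid list passed (adjusted p = 0.0497).

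The F test over the 3 groups called 0 genes in limma (smallest adjusted p = 0.985), and 453 had an unadjusted p under 0.05. The responses to the doses correlated across genes with r = 0.708. Simulated groups with no change, set against shared simulated saline arrays, gave r = 0.499, with a range of 0.413 to 0.597. The responses had the same sign for 75.5% of genes, against 66.7% in the simulations, with a range of 65.7% to 68.0%. The covariance was 0.124, which was 0.0132 above the simulated mean of 0.111 and within the simulated range of 0.0873 to 0.149. The difference between the 2 saline arrays alone would bring a covariance of 0.152, above the observed value. Among genes with an unadjusted p under 0.05, 94 were higher and 52 lower at both doses, where independent lists give 6.18 and 4.03 and the simulations gave 107 in each direction. The 2 saline arrays were not split between the doses, since each part would hold 1 array. The shared saline arrays may account for all of the covariance. Simulated genes varied independently, so the simulated ranges of r and of the shared signs may be too narrow. How much of the correlation and of the shared signs comes from the shared saline arrays therefore cannot be told.

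The other 13 lists were not called in any comparison by camera in the fit to all arrays without a covariate (smallest adjusted p = 0.0592). They were heat shock proteins, the unfolded protein and integrated stress response, p53 targets and apoptosis, inflammatory cytokines, immediate early genes, autophagy and lysosome, MHC class II presentation, lymphoid chemokines, T cells, NK and cytotoxic cells, dendritic cells, fibroblasts and smooth muscle, and adipocytes. In that fit their medians lay between −0.17 and 0.17 at 5 µmol/kg and between −0.27 and 0.11 at 10 µmol/kg, relative to saline. The acinar covariate brought a call of autophagy and lysosome genes, higher at 10 than at 5 µmol/kg (median 0.242). The camera adjusted p was 0.0133, and 0.827 with an estimated correlation. On only the arrays with high acinar signal, MHC class II medians were 0.375 at 5 and 0.575 at 10 µmol/kg. The T cell median there was 0.328 at 10 µmol/kg. Between the 2 arrays with low acinar signal the medians had the opposite sign, −0.385 for MHC class II and −0.157 for T cells. The MHC class II list had a mean of 8.928 on saline array 1 and 8.321 on saline array 2. Saline and 10 µmol/kg had 1 array each at either acinar level, so only medians are given. The chaperone Hspa8 differed by −0.48 ± 0.26 and −0.21 ± 0.26 (opposite in sign by 1 of its 2 other probes), Herpud1 of the unfolded protein response by −0.61 ± 0.26 and −0.30 ± 0.26, the p53 target Sesn1 by −0.13 ± 0.26 and 0.21 ± 0.26, and the invariant chain Cd74 by −0.10 ± 0.38 and 0.21 ± 0.38 at 5 and 10 µmol/kg. Another probe of Cd74 was opposite in sign at 5 µmol/kg. Satb1 of the T cell list differed by −0.77 ± 0.43 and −0.10 ± 0.43, and Nkg7 of the cytotoxic list by 0.55 ± 0.25 and 0.53 ± 0.25. None of these genes passed.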

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

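The alternatives with the acinar genes as a covariate, with the arrays selected by acinar signal and with the replicate numbers of 5 µmol/kg exchanged were chosen after seeing the data, and all others were planned. Where no cause is named below, the cause was not tested. The 0 gene calls held in 133 of 146 recomputed counts, among them each fit without 1 array, in which a lone array is assumed to vary like the other groups. The 133 include 7 counts that asked for a 2-fold difference besides the adjusted p, which could only be 0 once no gene had passed. With every probe tested on its own, 1 probe was lower at 10 than at 5 µmol/kg. At an unadjusted p under 0.05 with a 2-fold difference, which does not correct for the number of tests, 241 genes were higher and 229 lower at 5 µmol/kg, 31 and 12 at 10 µmol/kg, 9 and 16 at 10 against 5 µmol/kg, and 240 differed in the F test. On only the 4 arrays with high acinar signal, 175 genes were higher and 112 lower at 5 µmol/kg, 195 and 111 at 10 µmol/kg, 0 at 10 against 5 µmol/kg, and 201 in the F test. In that fit saline and 10 µmol/kg had 1 array each, and the spread came from the 2 arrays at 5 µmol/kg alone, which differed least.

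List calls moved more. With an estimated correlation, and by fry, 0 lists were called higher and 0 lower at 5 µmol/kg, at 10 µmol/kg and between the doses. In the simulations these tests recovered a shifted list in 0 and 3 of 20 runs, so their 0 calls say little about stability. At 5 µmol/kg the lists called lower numbered 1 with the authors' deposited values and 1 with genes detected on all 6 arrays. At 10 µmol/kg they numbered 4 with no filter on dim probes. Between the doses, the lists called higher numbered 3 with no background correction, 2 with the authors' deposited values and 3 with genes detected on all 6 arrays, and those called lower 5 with no filter and 5 with the acinar covariate. On the 4 arrays with high acinar signal, 4 lists were higher at 5 µmol/kg, 3 were lower at 10 µmol/kg and 8 were higher at 10 than at 5 µmol/kg. Leaving out 1 array gave 5 to 9 lists higher and 0 to 5 lower at 5 µmol/kg, 0 to 3 lower at 10 µmol/kg, and 0 to 8 higher and 4 to 8 lower between the doses. Of the lists called, 0 of 13 at 5 µmol/kg, 2 of 7 at 10 µmol/kg and 2 of 13 between the doses were called in all 6 such fits.

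Some medians turned direction. On the 4 arrays with high acinar signal the median at 5 µmol/kg was −0.097 for NRF2 genes, −0.12 for cell cycle genes, −0.048 for erythroid cells and −0.87 for acinar cells, that of erythroid cells at 10 µmol/kg was −0.50, and that of acinar cells was 0.24 at 10 against 5 µmol/kg. With the acinar covariate NRF2 genes were at 0.029 between the doses. Leaving out 1 array at a time, medians at 5 µmol/kg ran from −0.097 to 0.35 for NRF2 genes, −0.12 to 0.97 for cell cycle genes, −0.048 to 0.79 for erythroid cells and −0.87 to 7.70 for acinar cells. At 10 µmol/kg those of erythroid cells ran from −0.14 to 0.57. Between the doses they ran from −0.0027 to 0.52 for glucocorticoid-responsive genes, −0.40 to 0.11 for erythroid cells and −7.49 to 0.24 for acinar cells. Leaving out 1 array, Mt1 ran from −0.87 to 0.82 at 5 µmol/kg and from −1.0 to 0.69 at 10 µmol/kg. Mt2 ran from −0.50 to 0.45 at 5 µmol/kg, from −0.74 to 0.20 at 10 µmol/kg and from −0.51 to 0.027 between the doses, and Hmox1 from −0.11 to 0.48 between the doses. At 5 µmol/kg Mt2 was 0.0075 with no background correction and 0.15 with the authors' deposited values. Between the doses Mt1 was 0.21 and Mt2 0.098 with the acinar covariate, and Mt2 was 0.024 on the 4 arrays. The correlation of the dose responses was 0.708, with 0.769 over genes detected on all 6 arrays and 0.624 for the deposited values. Dim probes such as that of Mt2 lie near the background, where the signal limits the precision.

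Arrays of different groups shared replicate numbers, but the labels do not tie a number to a day or batch. Deviations from the group means correlated with −0.276 between saline and 5 µmol/kg, 0.579 between saline and 10 µmol/kg and −0.109 between the doses. The numbers thus went together for saline and 10 µmol/kg, and not for 5 µmol/kg. These values do not exclude a day or batch shared by arrays of saline and 10 µmol/kg. With the replicate block 0 genes were called in each comparison, and 5 list calls were lost. Lists called lower numbered 2 at 5 µmol/kg, 2 at 10 µmol/kg and 7 at 10 against 5 µmol/kg, and 2 lists were higher at 10 than at 5 µmol/kg. With the numbers of the 5 µmol/kg arrays exchanged, 0 genes were called in each comparison.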

Other observations

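The tests of a response to cadmium, of the acinar covariate, of 2-fold changes and of Mt1 were chosen after the results were seen. Arrays within groups differed in more than acinar genes. The brightest probe of the MHC class II gene H2-Ab1 read 10.67 on saline array 2 and between 11.80 and 12.33 on the other 5 arrays. The interferon gene Ifit3 read 10.07 on array 2 at 5 µmol/kg and between 7.05 and 7.37 on the other 5 arrays. The insulin gene Ins2, from pancreatic islets, was detected on the 4 arrays with bright acinar genes, at log2 signals of 8.68, 6.39, 5.96 and 5.52. Unnamed probes had a mean log2 signal of 6.70 on saline array 1 and 6.63 on array 1 at 10 µmol/kg, and of 6.49 to 6.54 on the other 4 arrays. No probe of the X-inactivation transcript Xist was detected on any array, and 1 probe of the Y-linked Kdm5d was detected on 4.

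The first pattern weighed was the bright acinar signal on 4 of the 6 arrays. A response to cadmium does not account for it, because the 24 genes had a median log2 difference of 8.44 between the 2 saline arrays, or at least 8.32 with the 17 genes not detected on saline array 1 set to the detection limit. Pancreatic tissue taken with some spleens is a candidate explanation, and 14 further acinar genes that had not been looked at were listed for a test. Only 6 of the 14 were measured, 5 of them were higher on the 4 arrays, and their median difference of 0.889 lay below the limit of 1 set for the explanation and above the limit of 0.5 set against it. Of the 24 genes, Cela2a at 14.34 and Amy2a5 at 14.39 on saline array 2 were near the top of the scale. Of the 6 further genes, Rbpjl, Aqp12 and Slc39a5 were detected only on the 4 arrays with bright acinar genes. Bhlha15, Tmem97 and Itpr3 were detected on all 6 arrays, and Itpr3 was lower on the 4 (−1.27). By the limits set, the test did not decide the source.

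The second pattern was that no gene passed. With the acinar level as a covariate, 0 genes passed in the 3 comparisons. That fit lowered the median standard deviation of genes from 0.282 to 0.216, with 2 residual degrees of freedom in place of 3. Taking out the acinar spread in this way brought no call. With fewer degrees of freedom, the fit cannot tell whether that spread had hidden calls. Of 4-fold changes, the simulations recovered at least 83.5% in each comparison. Their genes varied independently, with 200 changed genes planted, unlike the real arrays, which shared a strong structure. In the real fit Cyp4b1-ps2 differed 3.86-fold at 5 µmol/kg without passing (adjusted p = 0.525 in limma's moderated test). Whether 2 arrays per group are too few for 4-fold changes therefore cannot be told from the simulations. For 2-fold changes at most 6.64% were recovered without the covariate, so changes of that size may have gone without a call. The fit with the covariate recovered 33.5% to 46.9% in simulations of the same kind and also called 0 genes. The 15 ways to pair the 6 arrays are too few for a share under 0.05. Camera with the preset correlation made 33 list calls in the real grouping and 15 to 39 in the others. The real grouping included, 4 were at 33 or more. Many lists were thus called however the arrays were grouped, unlike in the simulations of independent genes. The F test gave 453 genes at an unadjusted p under 0.05 in the real grouping and up to 3166 in the others, with 8 at 453 or more, the real one included. The 3 groupings that put saline array 1 with array 1 at 10 µmol/kg called 1968 to 2218 genes over the 3 comparisons and the real grouping 0, which points to a structure of the samples, as these arrays had already been seen to stand apart, and does not tell what it comes from.

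The third pattern was Mt1, which was no higher in the cadmium groups. Saturation of its probe does not explain this, because its highest signal was 34.6% of the highest on the arrays. Mt1 carried in by pancreatic tissue may play a part, as the saline array with acinar signal was 1.69 higher than the other, but at 10 µmol/kg the array with acinar signal was −0.211 relative to its partner, and with a standard deviation of 0.73 for the difference of a pair, carried-in Mt1 and spread between samples cannot be told apart. No biological explanation was tested, since every array was taken at 24 h.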
